A study of Homo sapiens with 12 samples.

How the data were processed

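Total RNA from 12 samples of PC9 cells was measured on 12 single-colour Illumina bead arrays. The samples fall into 4 groups of 3 by their titles: PC9 alone with DMSO, PC9 alone with gefitinib, PC9 in co-culture with MRC-5 cells without gefitinib, and PC9 in co-culture with gefitinib. Per the labels, gefitinib was used at 0.5 µM from 24 h, the co-culture ran for 48 h through inserts with 1 µm pores, and the medium held 10% FCS. The same treatment text stands on every sample, and it places washes with PBS between gefitinib and the co-culture in EMEM. All 6 co-culture titles, and 0 of the 6 monoculture titles, end in WH, which the sources used here do not explain. The medium of the monocultures during those hours, a vehicle in the co-culture without gefitinib, and whether gefitinib was present during the co-culture are not given in the sources used here.

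The deposited table of unprocessed values holds, for each array, a signal column in units of intensity, which the authors neither logged nor normalized between arrays. Beside each signal column the deposited table gives a detection p-value per probe, and how the authors computed it is not given in the sources used here. A second deposited table holds values normalized by the authors, on a linear intensity scale. The authors' normalization method, scanner settings and image processing are not given in the sources used here. Each column of the second table was checked against the unprocessed signals and matched its own array best for 12 of 12 arrays, with a lowest Spearman correlation of 0.99993.

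The main analysis started from the unprocessed signals. Of 48107 probes, 5 lacked a value, and the other 48102 were background-corrected with the neqc function of limma 3.58.1 in R 4.3.3. That function fits a normal-exponential model with the background taken from the detection p-values, adds an offset of 16, applies quantile normalization and takes log2. Probes with a detection p-value under 0.05 on at least 3 of 12 arrays were kept, which left 25510. Probes were named from a platform annotation table, in which 30112 probes had 1 gene, 8 had several and 17982 were not listed. The 7221 passing probes without a gene were left out. For each gene with several passing probes the brightest was used, which gave 13514 genes, 3677 of them with several probes. Gene symbols were checked against RefSeq, which updated 0 of them and had no match for 39.

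Group means were fitted with limma over all 12 arrays, with 8 residual and 3.3 prior degrees of freedom. The SE given with a change is the moderated one from this fit. It pools the spread of all 4 groups, so it is not the spread of the compared groups alone. Moderated tests were made of 5 contrasts: gefitinib in monoculture, gefitinib in co-culture, co-culture without gefitinib, co-culture with gefitinib, and the difference between both gefitinib effects. Each test was two-sided, and p-values were adjusted by Benjamini-Hochberg over all genes with a threshold of 0.05. Of 41 gene lists, 40 had at least 5 tested members and were tested with camera, which compares a list with all other genes, at a preset correlation of 0.01 and with an estimated correlation as an alternative. Of the 829 listed genes, 776 had a named probe. The 41 lists, the comparisons with their tests, the alternatives and the rule for named genes were fixed before the data were examined, and the closing section names the tests that were not. Correlations across genes are given without a p-value, since genes are not independent replicates. Their errors are the SD over fits without 1 array at a time, scaled up by the root of the 12 arrays.

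The rule named, per comparison, the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold whose groups of arrays did not overlap. It added up to 4 members with the smallest p-value from each list described, counterexamples, and a fixed set of genes around EGFR signalling, growth and cytokines. Of that set, FGFR1 and ZEB1 did not pass the filter, AREG had no named probe, and 1 item is not reported here. Where all probes of a gene were below background on every array of a group, its fold is given as a lower bound against the dimmest detected probes of those arrays, except in the difference between both effects, where no bound was computed. Among 612 calls of named genes, 244 had several probes, and in 0 of them did another probe change significantly the other way. In 23 calls some passing probe had the other sign without being significant, as for RETREG1, SPRY4 and ERBB2 in monoculture.

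The alternatives were no background correction, median scaling in place of quantile normalization, the authors' normalized values, no filter, a strict filter (detection p-value under 0.01 on all 3 arrays of a group), the mean of a gene's probes, the replicate number as a block, array weights, only the compared groups in the fit, a fold of at least 1.5 beside the threshold, and leaving out each array in turn. A block for the chip could not be fitted, since chips are not named in the sources used here. The fits were tested on simulated, already normalized gene values with independent noise and known changes in the monoculture contrast over 13514 genes. Of genes changed by 0.5, 1 and 2 log2 units, 33.33%, 76.12% and 100% were recovered, 4.19% of calls were false, and 0 genes were called in an unchanged contrast. The earlier processing and correlation between genes were not simulated. The simulation gave 167 calls, against 5511 in the real contrast, so these shares need not hold there. The labels do not state separate cultures for the 3 samples of a group, so the p-values measure only the spread between these samples. The number of arrays limits the precision: the median standard error of a log2 change was 0.1425, and 0.2015 for the difference between both gefitinib effects.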

Results

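Transcript levels were measured in PC9, a lung adenocarcinoma line with an activating EGFR mutation that makes it sensitive to EGFR inhibitors such as gefitinib. The cells grew alone or in the same well as MRC-5, a line of lung fibroblasts held apart by a porous insert. Each of the 4 groups held 3 arrays: DMSO alone, gefitinib alone, co-culture, and co-culture with gefitinib. Between 20917 and 22820 probes per array were above background, mean signals ran from 370.9 to 443.8 intensity units, and the mean background ran from 92.45 to 98.3. Within groups, arrays correlated at 0.9886 to 0.9909 across genes. The first principal component held 59.3% of the variance. Its group means were -31.1 ± 0.406 (SD, n = 3) with DMSO, 43.1 ± 0.43 with gefitinib alone, -28.8 ± 0.507 in co-culture and 16.9 ± 4.38 in co-culture with gefitinib.

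**Figure D1:**
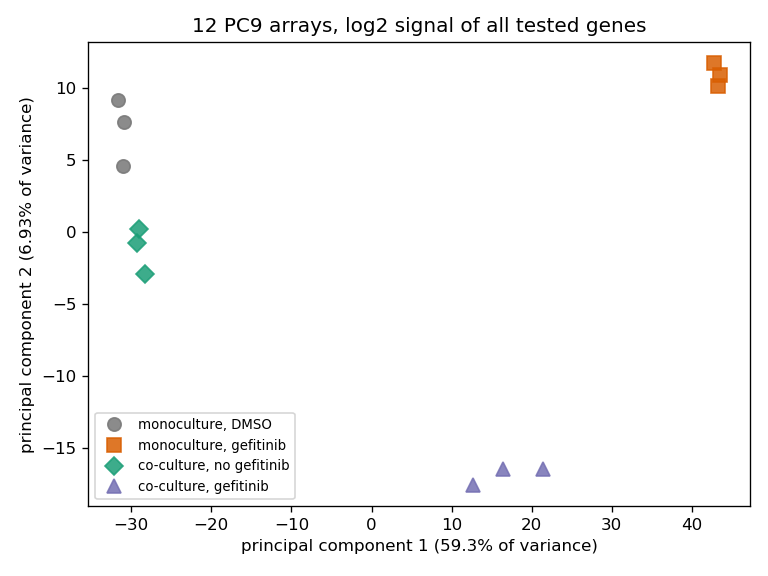
First against second principal component (in log2 units) of the 12 arrays, 1 point per array, coloured by group. The 3 arrays with gefitinib alone lie between 42.7 and 43.5 on the first component, those of co-culture with gefitinib between 12.7 and 21.4, those of co-culture without gefitinib between -29.3 and -28.3, and those with DMSO between -31.6 and -30.9.

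The first comparison asked which transcripts differed with gefitinib in PC9 grown alone. Genes that ERK signalling downstream of EGFR switches on fell. The ETS transcription factor ETV5 fell by 4.05 ± 0.15 log2 units (SE, n = 3 arrays per group), its relative ETV4 fell by 3.73 ± 0.18, and the ERK phosphatase DUSP6 fell by 3.45 ± 0.12. SPRY4, a feedback inhibitor of receptor signalling, went from a log2 level of 7.32 to 4.58, where it was above background on 0 of 3 arrays. The largest rises were those of ATP6V1B1, a proton pump subunit, by 5.29 ± 0.24, VTCN1, an immune checkpoint ligand, by 5.07 ± 0.16, RETREG1, a receptor for autophagy of the endoplasmic reticulum, by 5.02 ± 0.19, and OLR1, a scavenger receptor, by 5.01 ± 0.13.

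Other large rises were those of PTGS2, the inducible cyclooxygenase, by 4.20 ± 0.13, TAGLN, an actin-binding protein, by 4.13 ± 0.17, IL32 by 4.03 ± 0.24, FOLR1, a folate receptor, by 3.93 ± 0.21, RGL1 by 3.90 ± 0.14 and TNNC1 by 3.89 ± 0.13. IGFBP5 was at least 18.3-fold and TCIM at least 14.1-fold higher, both below background with DMSO. Large falls were seen for TGM2, a transglutaminase (-3.52 ± 0.11), MALL (-3.50 ± 0.11), TOX2 (-3.45 ± 0.17), the integrin ITGA6 (-2.82 ± 0.17), the chloride channel ANO1 (-2.76 ± 0.11), CAPN8 (-2.67 ± 0.16) and the lipase LIPG (-2.66 ± 0.14). The peroxisomal oxidase ACOX2 was at least 12.4-fold lower. With DMSO, VTCN1 and IL32 were above background on 1 of 3 arrays and ATP6V1B1, FOLR1 and WIPI1 on 2, as was DUSP6 with gefitinib, so that the sizes and ranks of these changes depend on the background. BMF, a pro-apoptotic BCL2 family member, rose by 2.82 ± 0.12, while BCL2L11 differed by -0.28 ± 0.15 and did not pass the test (adjusted p = 0.149 by limma). Among receptors, ERBB3 rose by 1.00 ± 0.09 and ERBB2 by 0.76 ± 0.10, while EGFR fell by 0.62 ± 0.09 and AXL fell by 1.02 ± 0.12. MET rose by 0.48 ± 0.14, a call that ended with median scaling (0.25, adjusted p = 0.344 by limma) and without 3 single arrays (adjusted p from 0.0523 to 0.072). The growth genes CCND1 (-0.73 ± 0.09), MYC (-0.90 ± 0.10) and MKI67 (-1.19 ± 0.13) fell, and the cell cycle inhibitor CDKN1B rose by 0.78 ± 0.10. IL6 rose by 2.01 ± 0.23, STAT3 by 1.09 ± 0.11 and CDH1 by 1.06 ± 0.09, and VIM fell by 0.92 ± 0.17.

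Among the fixed lists, all 32 tested mitosis genes fell (32 adjusted over the list alone), with a median of -1.27, among them MAD2L1 (-1.87), TTK (-1.68) and CENPA (-1.49). Of 30 tested DNA replication genes 27 fell and 3 did not pass (28 fell, adjusted over the list alone), with a median of -1.31, as in CDC25A (-1.85) and GINS2 (-1.76). Of 22 ERK output genes 18 fell, 2 rose (EPHA4 and PLAUR) and 2 did not pass, the same counts as adjusted over the list alone, with a median of -1.72. Of 25 ribosome biogenesis genes 21 fell and 4 did not pass, 21 also adjusted over the list alone, with a median of -0.76, as in BOP1 (-1.53) and NOP56 (-1.32). Of the 36 tested type 1 interferon genes 30 rose and 6 did not pass (31 rose, adjusted over the list alone), with a median of 0.93, as in EPSTI1 (2.13), MX1 (1.74) and IRF9 (1.58). Of 13 MHC class 1 genes 11 rose, also 11 adjusted over the list alone, with a median of 1.36, among them HLA-B (3.09), HLA-F (2.10) and the peptide-loading protein TAPBP (1.71). Of 23 lysosome and autophagy genes 18 rose and 1 fell (18 and 1 adjusted over the list alone), with a median of 0.51, as in WIPI1 (3.30) and GABARAPL1 (2.25). Of 23 epithelial genes 13 rose and 3 fell (13 and 3 adjusted over the list alone), with a median of 0.38, as in ELF3 (1.61) and CLDN1 (1.54). The camera adjusted p was 2.71e-22 for mitosis, 6.29e-18 for replication, 1.56e-11 for ERK output, 2.77e-08 for ribosome biogenesis, 1.8e-10 for interferon, 5.4e-08 for MHC class 1, 2.31e-06 for lysosome and 0.00144 for epithelial genes. These 8 lists also passed with an estimated correlation.

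A further 6 lists passed camera with the preset correlation alone. JAK/STAT3 genes had a median of 0.80 (10 higher and 2 lower of 19, also adjusted over the list alone), as in the complement gene CFB (3.22), with an adjusted p of 0.0105, and adjusted p = 0.0552 with an estimated correlation. FOXO and receptor feedback genes had a median of 0.58 (9 higher and 1 lower of 16, also adjusted over the list alone), as in CITED2 (3.01) and PIK3IP1 (2.86), with an adjusted p of 5.54e-04, and adjusted p = 0.0552 with an estimated correlation. Cell cycle exit genes had a median of 0.78 (9 higher and 2 lower of 13, also adjusted over the list alone), as in CDKN2B (2.98) and TXNIP (1.55), with an adjusted p of 0.0133, and adjusted p = 0.0553 with an estimated correlation. MHC class 2 genes had a median of 0.87 (4 of 5 higher, also adjusted over the list alone), as in CD74 (2.22), with an adjusted p of 0.0195, and adjusted p = 0.134 with an estimated correlation. Without the filter that median was 0.02 (adjusted p = 0.0616). Drug tolerance and stemness genes had a median of 0.45 (10 higher and 5 lower of 17, also adjusted over the list alone), as in IGFBP3 (2.38) and CD24 (2.28), with an adjusted p of 0.0421, and adjusted p = 0.145 with an estimated correlation. That call also ended without DMSO array 2 (adjusted p = 0.0523), with the strict filter (0.0584), with the replicate number as a block (0.0548) and with only the compared groups in the fit (0.0561). Glycolysis genes had a median of -0.38 (13 lower and 3 higher of 19, also adjusted over the list alone), as in HK2 (-1.57) and ENO2 (-1.57), with an adjusted p of 0.0256, and adjusted p = 0.134 with an estimated correlation. Immediate early genes were split: 2 of 11 rose, ATF3 (2.54) and JUNB (0.98), and 4 fell, EGR1 (-1.18) and KLF2 (-1.13) among them, with a median of -0.44 and an adjusted p of 0.569 (2 higher and 5 lower adjusted over the list alone).

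The other 25 lists did not pass camera, with adjusted p from 0.0515 for BMP response genes (median 0.55) to 1 for cholesterol synthesis genes (median -0.01). In the BMP list 5 of 10 genes rose, among them ID3 by 3.68 ± 0.16, and 2 fell (5 and 2 adjusted over the list alone). That list passed camera with no background correction (adjusted p = 0.0297), with median scaling (0.00897), with the authors' values (0.0295), with no filter (0.03), with array weights (0.0474) and without 3 single arrays (0.0206 to 0.0404). NF-kB genes (median 0.18, camera adjusted p = 0.0758) passed with no background correction (0.0412), median scaling (0.0158), the authors' values (0.0429) and no filter (0.0471), and without 3 single arrays (0.03 to 0.039). Fibroblast markers had 6 of 18 tested members higher and 0 lower in this monoculture (6 adjusted over the list alone), among them TAGLN, COL5A1 (2.20 ± 0.12), MFAP5 (1.52 ± 0.14) and SPARC (1.42 ± 0.11), with a camera adjusted p of 0.106. They passed with no background correction (0.0433), median scaling (0.0194), the authors' values (0.0495) and the strict filter (0.0267). With median scaling, heat shock genes (-0.53, camera adjusted p = 0.0158) and ribosomal protein genes (-0.31, 0.0303) also passed. Of the leukocyte markers only 4 were tested, too few for camera: TYROBP and FCER1G were above background on 0 arrays of every group, CSF1R on all 12 arrays, and CD14 on 3 of 3 arrays in both gefitinib groups and 1 of 3 in the others. Medians and means were of opposite sign for the lung differentiation list (0.004 and -0.03), the BCL2 family (-0.14 and 0.06) and the mesenchymal genes (-0.19 and 0.12), none of which passed.

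In all, 5511 of 13514 genes passed limma in monoculture, 2846 higher and 2665 lower, and 3289 of them changed by at least 1.5-fold. Median scaling in place of quantile normalization moved the median of all genes to -0.12, and the share of higher genes among those past the threshold from 51.64% to 32.96%. The medians of the 14 lists past camera kept their sign under it, and those of epithelial (0.12), lysosome (0.31), drug tolerance (0.20) and glycolysis genes (-0.64) moved by over 1.5 times. Without background correction, and with similar values from the authors' normalization, so did ERK output (-1.13), interferon (0.60), JAK/STAT3 (0.30) and MHC class 2 genes (0.34), and without the filter JAK/STAT3 (0.21) and drug tolerance genes (0.25).

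**Figure D2:**
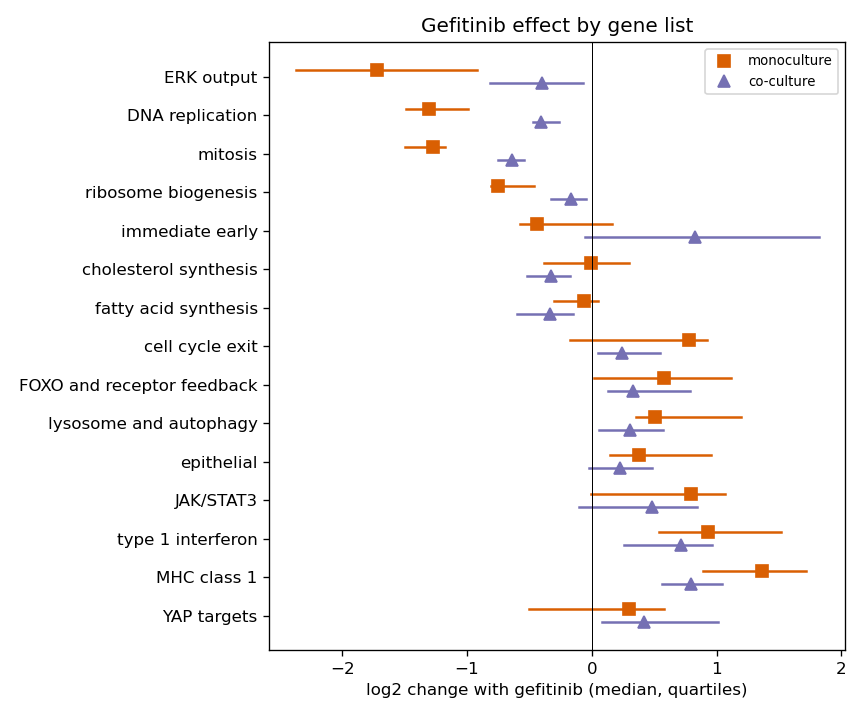
Median log2 change with gefitinib of 15 gene lists, with lines from the first to the third quartile, in monoculture (squares) and in co-culture (triangles). ERK output has a median of -1.72 in monoculture and -0.40 in co-culture, and mitosis -1.27 and -0.64, and each plotted list that passed camera in a culture kept the sign of its median there under median scaling.

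The second comparison asked the same in co-culture. The ERK output genes and cell division genes were lower with gefitinib here too, by less, and immediate early genes were higher. ETV5 fell by 2.02 ± 0.15 (SE, n = 3 arrays per group), ETV4 fell by 2.08 ± 0.18 and DUSP6 fell by 1.99 ± 0.12. The early response transcription factors EGR1 and FOS rose by 2.21 ± 0.10 and 1.79 ± 0.14, and the neutrophil chemokine CXCL8 rose by 2.09 ± 0.23. SCD, the desaturase that makes monounsaturated fatty acids, fell by 2.80 ± 0.20.

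The largest rises were those of ATP6V1B1 (5.07 ± 0.24), TAGLN (4.79 ± 0.17), OLR1 (4.37 ± 0.13), VTCN1 (4.15 ± 0.16), PTGS2 (4.05 ± 0.13), TCIM (3.22 ± 0.18), RGL1 (3.17 ± 0.14), FRAS1 (3.15 ± 0.12), RETREG1 (3.15 ± 0.19), the complement protease C1S (3.09 ± 0.23) and FOLR1 (2.97 ± 0.21). PDZK1IP1 was at least 8.33-fold higher. TAGLN and TCIM were above background on 1 of 3 arrays of the co-culture without gefitinib and FOLR1 on 2, so that the sizes and ranks of these rises depend on the background. The falls included ACOX2 (-3.40 ± 0.23), TH, the rate-limiting enzyme of catecholamine synthesis (-2.33 ± 0.21), MILR1 (-2.32 ± 0.26), TOX2 (-2.29 ± 0.17), CAPN8 (-2.26 ± 0.16), TRIB2 (-1.98 ± 0.15), LIPG (-1.92 ± 0.14) and EFNB1 (-1.89 ± 0.13). BMF rose by 1.96 ± 0.12 and MCL1, an anti-apoptotic relative, by 0.53 ± 0.10. ERBB2 rose by 0.49 ± 0.10 and ERBB3 by 0.35 ± 0.09, the latter not with the mean of its probes (adjusted p = 0.0724 by limma) or without arrays 1 or 2 of co-culture with gefitinib (0.0587 and 0.0566). AXL fell by 0.62 ± 0.12, a call that median scaling ended (-0.50, adjusted p = 0.0604). CCND1 (-0.01 ± 0.09), MYC (-0.16 ± 0.10) and EGFR (-0.17 ± 0.09) did not pass. CDH1 rose by 0.61 ± 0.09, IL6 by 1.57 ± 0.23 and STAT3 by 0.66 ± 0.11, and VIM fell by 0.83 ± 0.17.

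Of the mitosis genes 30 of 32 fell (31 adjusted over the list alone; median -0.64, camera adjusted p = 2.31e-20), as in CDC25C (-1.09) and KIF2C (-0.84). Of the DNA replication genes 16 of 30 fell (23 adjusted over the list alone; median -0.40, 2.63e-09), as in CCNE1 (-0.84). Of the ERK output genes 10 of 22 fell and EPHA4 rose, with 12 lower and 2 higher adjusted over the list alone, a median of -0.40 and a camera adjusted p of 8.3e-05. Of 11 immediate early genes 6 rose and KLF2 fell (7 higher and 1 lower adjusted over the list alone), with a median of 0.83 and a camera adjusted p of 1.13e-04. Beside EGR1 and FOS these were FOSB (1.85), ATF3 (1.99), JUNB (1.16) and ZFP36 (0.83). Type 1 interferon genes had 21 of 36 higher and 1 lower (24 and 1 adjusted over the list alone; median 0.71, 6.96e-11), as in EPSTI1 (1.37) and IFI6 (1.23). MHC class 1 genes had 11 of 13 higher (11 adjusted over the list alone; median 0.80, 1.74e-10), as in HLA-B (2.24), and MHC class 2 genes 4 of 5 (4 adjusted over the list alone; median 1.06, 2.64e-04), as in CD74 (1.92).

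Lipid synthesis lists were lower. Of 12 fatty acid synthesis genes 6 fell, also 6 adjusted over the list alone, with a median of -0.34 and a camera adjusted p of 2.7e-04. They included SREBF1 (-0.81), a regulator of lipid synthesis, and FASN (-0.75), the fatty acid synthase. Of 18 cholesterol synthesis genes 7 fell (9 adjusted over the list alone), with a median of -0.33 and an adjusted p of 1.07e-04, as in INSIG1 (-1.29) and MVK (-0.88). YAP target genes had 8 of 17 higher and 2 lower (10 and 2 adjusted over the list alone), a median of 0.42 and an adjusted p of 8.83e-04, as in CCN2 (1.64) and CCN1 (1.01). JAK/STAT3 genes had 9 of 19 higher and 2 lower (9 and 3 adjusted over the list alone; median 0.48, 8.83e-04), as in CFB (2.73). Glucocorticoid response genes had 5 of 10 higher (5 adjusted over the list alone; median 0.35, 6.27e-04), as in DUSP1 (2.47) and SGK1 (1.60). NF-kB genes had 9 of 24 higher and 2 lower (9 and 2 adjusted over the list alone; median 0.35, 0.00246), as in RELB (1.74). The lists of lysosome (median 0.31), FOXO and receptor feedback (0.33), cell cycle exit (0.24), epithelial (0.22), drug tolerance (0.38), TGF-beta response (0.15) and fibroblast marker genes (0.19) also passed upward, and glycolysis (-0.27) downward. With 18 fibroblast markers tested, 4 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.0106). The 4 were TAGLN, COL5A1 (1.89), SPARC (1.26) and MFAP5 (0.83), which also rose with gefitinib in monoculture.

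In co-culture 2710 genes passed limma, 1471 higher and 1239 lower, and 1411 of them changed by at least 1.5-fold. Of 40 lists 24 passed camera, and 21 with an estimated correlation. The other 3 were ribosome biogenesis (median -0.17, 5 of 25 lower and 1 higher, 6 and 1 adjusted over the list alone), hypoxia (median -0.13, 6 of 21 lower and 1 higher, also adjusted over the list alone) and BMP response (median 0.29, 3 of 10 higher and 1 lower, 5 and 1 adjusted over the list alone). They had adjusted p = 0.0801, adjusted p = 0.0628 and adjusted p = 0.0967 with an estimated correlation. Median scaling moved the median of all genes to 0.133 and the share of higher genes among those past the threshold from 54.28% to 83.71%. It turned the sign of 0 of these list medians, and ended the calls of several cell division genes (CDC45, POLE2, RRM1 and MKI67). It moved by over 1.5 times the medians of ERK output (-0.23), replication (-0.24), cholesterol (-0.13), glycolysis (-0.14), hypoxia (-0.06) and ribosome biogenesis genes (-0.05), and upward those of cell cycle exit (0.43), TGF-beta (0.32), BMP (0.45), epithelial (0.37), glucocorticoid (0.54) and fibroblast marker genes (0.34). Without background correction, and with similar values from the authors' normalization, the medians of interferon (0.43), MHC class 2 (0.44), JAK/STAT3 (0.21), NF-kB (0.18), YAP target (0.22) and fibroblast marker genes (0.10) were as much smaller, and without the filter those of JAK/STAT3 (0.11), MHC class 2 (0.39), drug tolerance (0.06), fibroblast marker (0.12) and glucocorticoid genes (0.19). With the strict filter those of fibroblast marker (0.50), TGF-beta (0.30) and hypoxia genes (-0.21) were larger in size, and the first and last also with only the compared groups in the fit (0.42 and -0.22). The fibroblast marker median was 0.29 with the mean of a gene's probes, and 0.32 and 0.09 without arrays 1 and 3 of co-culture without gefitinib. That of hypoxia genes was -0.21 without array 1 of co-culture without gefitinib and -0.22 without array 1 of co-culture with gefitinib. Lists of p53 targets and extracellular proteases, which did not pass (camera adjusted p = 0.0775 for both), did with no background correction (0.0492 for both), the first also with the authors' values (0.0491) and the strict filter (0.0488) and the second without 1 single array (0.0419).

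The third comparison asked how PC9 in co-culture without gefitinib differed from PC9 alone with DMSO. Few genes passed, and the epithelial list did not (median 0.03, camera adjusted p = 0.719). SCD rose by 1.55 ± 0.20 (SE, n = 3 arrays per group), ABCA1, the exporter of cholesterol, by 1.38 ± 0.10, and SREBF1 by 0.77 ± 0.11. The antimicrobial peptide DEFB1 rose by 1.49 ± 0.16, the adhesion proteins CEACAM5 and CEACAM1 by 1.20 ± 0.14 and 1.16 ± 0.18, the mucin MUC1 by 1.07 ± 0.10, the plasminogen activator PLAT by 1.05 ± 0.12 and AGR2 by 1.02 ± 0.14. TAGLN (-1.37 ± 0.17), the BMP target ID3 (-1.02 ± 0.16) and MFAP5 (-0.79 ± 0.14) fell.

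Further rises were those of ANXA4 (1.00 ± 0.17), CAPN5 (0.94 ± 0.15), WFDC3 (0.94 ± 0.13) and PPIB (0.88 ± 0.16), and further falls those of DCLK1 (-1.22 ± 0.22), MAP1B (-0.98 ± 0.15), CGB5 (-0.88 ± 0.14), MARCHF4 (-0.80 ± 0.09), OLR1 (-0.74 ± 0.13), HOXC8 (-0.71 ± 0.11) and CAPN7 (-0.68 ± 0.09). TGM6 was at least 1.68-fold lower, and LINC01364 went from a log2 level of 5.41 to 4.66, where it was above background on 1 of 3 arrays, as was TAGLN. The growth and signalling genes listed next did not pass limma. DUSP6 differed by 0.42 ± 0.12 (adjusted p = 0.184), ETV5 by 0.35 ± 0.15, MYC by 0.12 ± 0.10, CCND1 by -0.19 ± 0.09, MKI67 by -0.18 ± 0.13, EGFR by -0.25 ± 0.09, MET by 0.02 ± 0.14 and CXCL8 by 0.17 ± 0.23.

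Of 12 fatty acid synthesis genes 2 rose, SCD and SREBF1, with 3 higher adjusted over the list alone, a median of 0.18 and a camera adjusted p of 4.99e-04. JAK/STAT3 genes had 2 of 19 higher (3 adjusted over the list alone), BCL3 (0.68) and CEBPD (0.56), with a median of 0.12 and an adjusted p of 7.81e-04. YAP targets had a median of -0.35 and an adjusted p of 3.06e-06, with F3 the only member of 17 below the threshold over all genes and 7 adjusted over the list alone, ANKRD1 (-0.96 ± 0.19) among the largest differences. The call of F3 (-0.55 ± 0.10) rests on 1 of 2 nearly equally bright probes, the other of which differed by -0.0384, and it ended without any 1 of the 6 arrays, with its sign turned without DMSO array 1 (0.01). These 3 lists also passed with an estimated correlation. A further 8 lists passed with the preset correlation alone. Metallothionein genes had a median of -0.45 with 0 of 5 members past limma (2 lower adjusted over the list alone) and adjusted p = 0.0504 with an estimated correlation. Lung differentiation genes had a median of 0.12 with 3 of 14 higher (4 adjusted over the list alone) and adjusted p = 0.0504 with an estimated correlation. Ribosome biogenesis genes had a median of -0.19 with 0 of 25 past limma (1 lower adjusted over the list alone) and adjusted p = 0.051 with an estimated correlation. BMP response genes had a median of -0.17 with ID3 lower of 10 (1 adjusted over the list alone) and adjusted p = 0.151 with an estimated correlation. Cholesterol synthesis genes had a median of 0.14 with 0 of 18 past limma (3 higher adjusted over the list alone) and adjusted p = 0.119 with an estimated correlation. The ERK output (median 0.15), interferon (0.12) and MHC class 1 (0.16) lists had 0 members past limma over all genes or over the list alone, with adjusted p = 0.158, adjusted p = 0.216 and adjusted p = 0.295 with an estimated correlation. The cholesterol call also ended without DMSO array 3 (median 0.05, camera adjusted p = 0.0868), without co-culture arrays 1 (0.07, 0.0911) and 2 (0.12, 0.0822), with median scaling (0.0902) and with only the compared groups in the fit (0.0594). The ERK output call ended without 5 of the 6 arrays (0.0534 to 0.0805), with median scaling (0.0902) and with the mean of a gene's probes (0.0512). The interferon call ended without DMSO arrays 2 (0.0805) and 3 (median 0.07, 0.156) and co-culture array 2 (0.0579). The MHC class 1 call ended without 4 of the 6 arrays (0.0836 to 0.157), with median scaling (0.168), with the mean of a gene's probes (0.272) and with only the compared groups in the fit (0.0594). The BMP call ended without DMSO array 2 (0.091). The tests of immediate early, mitosis and DNA replication genes did not pass camera, with medians of 0.18, -0.05 and -0.003, but mitosis genes passed downward with median scaling (-0.16, adjusted p = 0.0178) and with the mean of a gene's probes (-0.06, 0.0248). Receptor tyrosine kinase, extracellular protease and MHC class 2 lists did not pass (camera adjusted p = 0.0767, 0.0832 and 0.0971), and did under 2, 3 and 3 alternatives (0.0224 to 0.0492).

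In all, 48 genes passed limma, 32 higher and 16 lower, with 1599 at an unadjusted p under 0.05. The count was 18, 21 and 18 without DMSO arrays 1, 2 and 3, 22, 26 and 11 without co-culture arrays 1, 2 and 3, 17 with median scaling, which moved the median of all genes to -0.0989 and the share of higher genes from 66.67% to 35.29%, and 4 with only the compared groups in the fit. Of 30 named genes called here, 7 kept their call without each array in turn (DEFB1, ABCA1, CEACAM5, MUC1, PLAT, MARCHF4 and TAGLN), and 3 kept it under every alternative run (DEFB1, ABCA1 and MUC1). The call of SCD ended without co-culture array 3 (adjusted p = 0.0502), that of SREBF1 with median scaling (0.115) and without 4 single arrays (0.0502 to 0.0595), and that of AGR2 with the mean of its probes (0.514). Median scaling moved by over 1.5 times the medians of fatty acid (0.08), ERK output (0.03), cholesterol (0.01), interferon (0.04), MHC class 1 (0.05), BMP (-0.28) and ribosome biogenesis genes (-0.31), and no background correction, with similar values from the authors' normalization, those of YAP target (-0.16), metallothionein (-0.23), BMP (-0.10) and lung differentiation genes (0.08). The last median was 0.06 without the filter, 0.35 with the strict filter and 0.36 with only the compared groups in the fit, where that of JAK/STAT3 genes was 0.22. Without single arrays the JAK/STAT3 median reached 0.24, that of BMP genes -0.32 and that of lung differentiation genes 0.08. With the mean of a gene's probes the median was 0.04 for MHC class 1 and -0.12 for ribosome biogenesis genes.

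**Figure D3:**
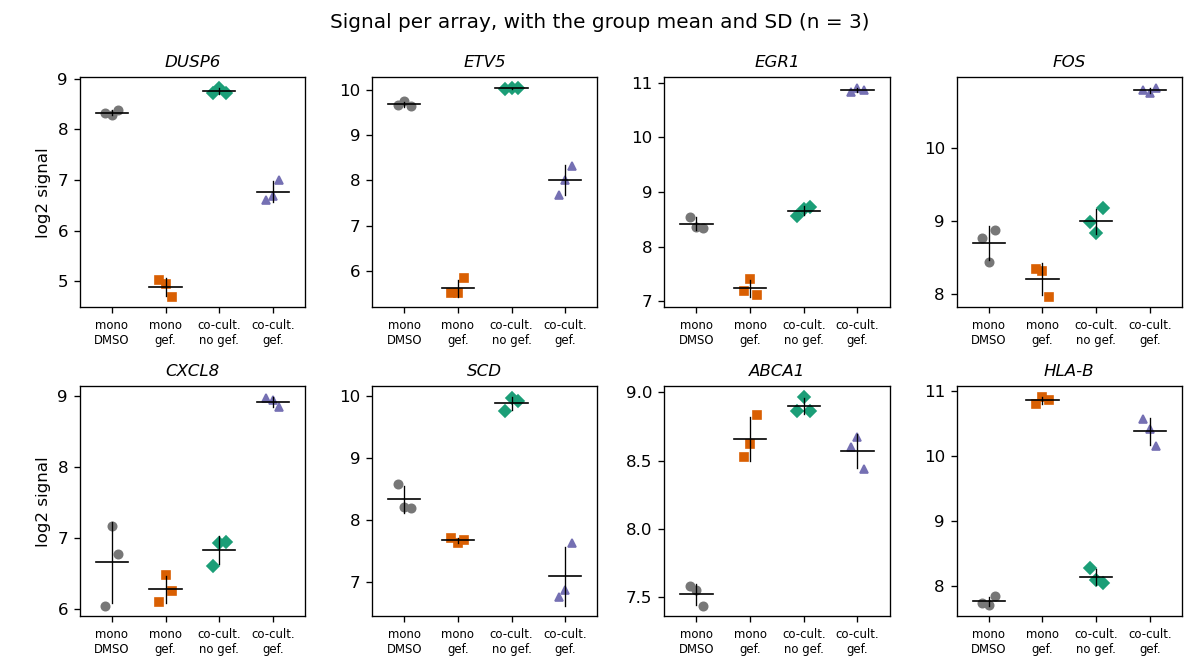
Log2 signal per array of 8 genes in the 4 groups, with the group mean as a bar and the SD as a vertical line (n = 3 arrays). EGR1 averaged 10.87 in co-culture with gefitinib and 7.23 to 8.66 in the other groups, DUSP6 4.88 with gefitinib alone and 6.76 in co-culture with gefitinib, and SCD 9.89 in co-culture without gefitinib.

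The fourth comparison asked how gefitinib-treated PC9 in co-culture differed from gefitinib-treated PC9 alone. Early response, ERK output and cell division genes were higher in co-culture. EGR1 rose by 3.63 ± 0.10 (SE, n = 3 arrays per group), CXCL8 by 2.65 ± 0.23, FOS by 2.58 ± 0.14, TGM2 by 2.43 ± 0.11 and ETV5 by 2.38 ± 0.15. DUSP6 rose by 1.88 ± 0.12, MYC by 0.86 ± 0.10 and CCND1 by 0.53 ± 0.09. The EGFR ligand HBEGF rose by 1.49 ± 0.13.

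Further rises were those of PHLDA1 (2.25 ± 0.12), MALL (2.20 ± 0.11), the AP-1 subunit FOSL1 (1.98 ± 0.14), SPRY2 (1.95 ± 0.11), DUSP5 (1.94 ± 0.11) and MAFF (1.91 ± 0.13), and SPRY4 went from 4.58, below background on all 3 arrays, to 6.58. The largest falls were those of NLRP7 (-2.15 ± 0.13), the inhibin subunit INHA (-2.10 ± 0.31), TPPP3 (-2.04 ± 0.15), ID3 (-1.87 ± 0.16), IL32 (-1.78 ± 0.24), RETREG1 (-1.69 ± 0.19), GASK1B (-1.62 ± 0.14), KANK4 (-1.49 ± 0.19), MFAP5 (-1.48 ± 0.14), TMEM52B (-1.47 ± 0.17), the histone gene H4C5 (-1.45 ± 0.20) and C4BPB (-1.41 ± 0.17). BMF (-0.67 ± 0.12), ERBB3 (-0.45 ± 0.09), CDKN1B (-0.55 ± 0.10), CDH1 (-0.43 ± 0.09) and STAT3 (-0.39 ± 0.11) fell, each a call that median scaling ended. MKI67 rose by 0.46 ± 0.13, a call that ended without any 1 of the 6 arrays. EGFR (0.20 ± 0.09), MET (-0.17 ± 0.14), AXL (0.29 ± 0.12), BCL2L11 (0.29 ± 0.15), MCL1 (0.25 ± 0.10), IL6 (-0.55 ± 0.23), VIM (-0.01 ± 0.17) and COL1A1 (-0.34 ± 0.27) did not pass limma.

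All 32 mitosis genes rose (32 adjusted over the list alone; median 0.59, camera adjusted p = 5.42e-25), and 27 of 30 DNA replication genes (27 adjusted over the list alone; median 0.87, 2.62e-26), as in CDC25A (1.37) and MCM10 (1.36). Of 22 ERK output genes 18 rose and EPHA4 fell (18 and 1 adjusted over the list alone; median 1.37, 1.65e-21). Ribosome biogenesis genes had 12 of 25 higher (17 adjusted over the list alone; median 0.33, 3.83e-08), as in BOP1 (0.64) and DDX21 (0.59). Immediate early genes had 5 of 11 higher and ATF3 lower (9 and 1 adjusted over the list alone; median 0.64, 6.55e-07), as in ZFP36 (0.92) and JUN (0.82). Lysosome and autophagy genes had 9 of 23 lower (15 adjusted over the list alone; median -0.29, 4.16e-07), as in ULK1 (-0.94) and GABARAPL1 (-0.86). Cholesterol synthesis genes had 5 of 18 lower (8 adjusted over the list alone), with a median of -0.22 and an adjusted p of 0.00145, and 0.0755 with median scaling. Epithelial genes had 6 of 23 lower and 1 higher (8 and 1 adjusted over the list alone), with a median of -0.25 that became 0.04 with median scaling (adjusted p = 0.00145, then 0.158). These 8 lists passed with an estimated correlation. Of 4 more that did not, the interferon list had 7 of 36 members lower (7 adjusted over the list alone; median -0.28), as in IFIT2 (-1.04) and EPSTI1 (-0.90), with adjusted p = 0.11 with an estimated correlation. MHC class 1 genes had 3 of 13 lower (5 adjusted over the list alone), with a median of -0.27 that became 0.02 with median scaling, and adjusted p = 0.11 with an estimated correlation. Cell cycle exit genes had 5 of 13 lower and 2 higher (8 and 2 adjusted over the list alone; median -0.47), as in CDKN2B (-1.05), with adjusted p = 0.0893 with an estimated correlation. BMP response genes had 4 of 10 lower and 1 higher (6 and 1 adjusted over the list alone; median -0.50), with adjusted p = 0.138 with an estimated correlation. That call also ended without gefitinib array 3 of the monoculture (adjusted p = 0.123) and without array 1 of co-culture with gefitinib (adjusted p = 0.0515).

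Fibroblast markers had 0 of 18 tested members higher and 3 lower by limma (0 and 4 adjusted over the list alone). THY1, LUM and COL3A1 were above background on 0 arrays of every group, COL1A2 on 1 array of each, and DCN and COL6A3 on 2 of 3 arrays here, against 1 and 0 with gefitinib alone. In all, 1820 genes passed limma, 960 higher and 860 lower, 829 of them by at least 1.5-fold, and 1168 and 1096 passed without arrays 2 and 3 of co-culture with gefitinib. Median scaling moved the median of all genes to 0.187 and the share of higher genes among those past the threshold from 52.75% to 91.15%. It moved by over 1.5 times the medians of lysosome (-0.05), interferon (-0.03), cholesterol (-0.02), cell cycle exit (-0.20), BMP (-0.24) and ribosome biogenesis genes (0.61). No background correction, with similar values from the authors' normalization, did so for ERK output (0.82), immediate early (0.38), cell cycle exit (-0.26), interferon (-0.16) and BMP genes (-0.30). The interferon median was -0.18 without array 3 of co-culture with gefitinib. The lung differentiation list (median 0.06) missed the threshold (camera adjusted p = 0.0502) and passed under 6 alternatives and without 4 single arrays (0.0139 to 0.0483). DUSP6 was above background on 2 of 3 arrays with gefitinib alone.

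The last comparison asked where both gefitinib effects differed. The difference was largest for EGR1, whose change was 3.40 ± 0.15 higher in co-culture (SE, n = 3 arrays in each of 4 groups), followed by CXCL8 (2.48 ± 0.33), TGM2 (2.41 ± 0.16) and FOS (2.28 ± 0.20). ERK output genes had smaller falls in co-culture, with differences of 2.04 ± 0.21 for ETV5, 1.46 ± 0.17 for DUSP6 and 2.16 ± 0.17 for PHLDA1. SCD, which rose with co-culture alone, had a difference of -2.14 ± 0.28 and ABCA1 of -1.47 ± 0.15. RETREG1, IL32 and TNNC1 rose less in co-culture, with differences of -1.87 ± 0.27, -1.71 ± 0.35 and -1.46 ± 0.19.

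The difference was also positive for MALL (2.09 ± 0.15), FOSL1 (2.05 ± 0.19), FOXD1 (1.92 ± 0.37), ANKRD1 (1.86 ± 0.27) and CCN2 (1.72 ± 0.14). DUSP4 (1.89 ± 0.31) and SPRY4 (1.60 ± 0.19) were above background on 0 of 3 arrays with gefitinib alone and FOXD1 on 1 of 3, so that their values depend on the background, and SPRY4 did not pass with the mean of its probes (adjusted p = 0.0782 by limma). It was negative for INHA (-2.14 ± 0.43), NLRP7 (-2.05 ± 0.19), TPPP3 (-2.04 ± 0.22), RGCC (-1.72 ± 0.21), GASK1B (-1.69 ± 0.20), IFIT2 (-1.46 ± 0.30) and WNT10A (-1.46 ± 0.32). Of these, GASK1B and WNT10A were above background on 0 of 3 arrays with DMSO, and NLRP7 on 0 of 3 in co-culture without gefitinib. Of the others, TPPP3 and IL32 were above background on 1 of 3 arrays and INHA on 2 of 3 in both groups without gefitinib, and DUSP6 on 2 of 3 with gefitinib alone. CCND1 and MYC had differences of 0.72 ± 0.13 and 0.74 ± 0.14. ERBB3 (-0.66 ± 0.12) and BMF (-0.86 ± 0.17) passed, and with median scaling did not (adjusted p = 0.402 and 0.124). EGFR (0.45 ± 0.13), MKI67 (0.64 ± 0.18), CDH1 (-0.45 ± 0.13), CDKN1B (-0.40 ± 0.14), BCL2L11 (0.39 ± 0.21), IL6 (-0.44 ± 0.32), STAT3 (-0.43 ± 0.15) and VIM (0.09 ± 0.23) did not pass.

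Of 22 ERK output genes 17 had a higher effect in co-culture (17 adjusted over the list alone; median difference 1.41, 0.70 with no background correction and 0.69 with the authors' values, camera adjusted p = 1.45e-18), of 30 DNA replication genes 25 (26 adjusted over the list alone; 0.85, 4.93e-24), of 32 mitosis genes 23 (32 adjusted over the list alone; 0.62, 7.01e-23) and of 25 ribosome biogenesis genes 10 (14 adjusted over the list alone; 0.54, 1.78e-10). Cholesterol synthesis genes had 4 of 18 lower (10 adjusted over the list alone; -0.42, 1.36e-04), as in INSIG1 (-0.86) and DHCR7 (-0.84), calls that median scaling ended for both genes and kept for the list. Lysosome genes had 6 of 23 lower (7 adjusted over the list alone; 2.3e-06), with a median of -0.32 that became 0.09 with median scaling, below the median of all genes. These 6 lists passed with an estimated correlation.

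Another 9 lists passed with the preset correlation alone. Immediate early genes had 5 of 11 higher and ATF3 lower (5 and 1 adjusted over the list alone; median 0.44, 6.75e-05), with adjusted p = 0.0535 with an estimated correlation. YAP targets had 4 of 17 higher and 1 lower (6 and 2 adjusted over the list alone; 0.33, 0.00211), with adjusted p = 0.0601 with an estimated correlation. Metallothioneins had 2 of 5 higher, MT1X and MT2A (2 adjusted over the list alone; 0.80, 0.0113), with adjusted p = 0.063 with an estimated correlation. Interferon genes had 5 of 36 lower (6 adjusted over the list alone; -0.35, 1.04e-04), with adjusted p = 0.0585 with an estimated correlation. MHC class 1 genes had 3 of 13 lower, HLA-B among them (6 adjusted over the list alone; -0.43, 2.29e-04), with adjusted p = 0.063 with an estimated correlation. Epithelial genes had 3 of 23 lower and 1 higher (6 and 1 adjusted over the list alone; 0.00456), a median of -0.24 that became 0.13 with median scaling, and adjusted p = 0.063 with an estimated correlation. Cell cycle exit genes had 4 of 13 lower and 1 higher (7 and 2 adjusted over the list alone; -0.43, 0.0253), with adjusted p = 0.0716 with an estimated correlation. Fatty acid synthesis genes had 3 of 12 lower (5 lower and 1 higher adjusted over the list alone; 0.0253), a median of -0.24 that became 0.15 with median scaling, and adjusted p = 0.0809 with an estimated correlation. FOXO and receptor feedback genes had 4 of 16 lower (4 adjusted over the list alone; 0.0385), a median of -0.22 that became 0.01 with median scaling, and adjusted p = 0.219 with an estimated correlation. Median scaling ended the calls of epithelial (camera adjusted p = 0.25), fatty acid (0.149) and FOXO genes (0.118), the strict filter those of fatty acid (0.0753) and FOXO genes (0.0658), and the mean of a gene's probes that of FOXO genes (0.0881). The calls of cell cycle exit, fatty acid and FOXO genes also ended without 1, 2 and 6 single arrays (0.0514 to 0.0833).

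In all, 983 genes passed limma, 532 higher and 451 lower, and 629 and 575 without arrays 2 and 3 of co-culture with gefitinib. Of the 983, 772 changed less in co-culture and in the same direction, 18 changed more in the same direction, and 193 had effects of opposite sign. Median scaling moved the median of all genes to 0.292, the count to 1668 and the share of higher genes from 54.12% to 95.08%. It brought the medians of interferon (-0.05), MHC class 1 (-0.02) and cholesterol genes (-0.02) close to 0 and that of cell cycle exit genes to -0.14, and raised those of mitosis (1.01), immediate early (0.76), ribosome biogenesis (0.92) and YAP target genes (0.56). Without background correction the medians were 0.21 for immediate early, 0.15 for YAP target, 0.32 for metallothionein (0.42 without the filter) and -0.14 for FOXO and receptor feedback genes. Without single arrays the median was 0.72 for immediate early, 0.22 for YAP target and -0.15 for fatty acid synthesis genes. Glycolysis (0.54), heat shock (0.48) and ribosomal protein genes (0.41) passed camera with median scaling alone (adjusted p from 0.0394 to 0.0453). Across genes, both gefitinib effects correlated at 0.79 ± 0.0301 (Spearman 0.678), with a slope of 0.54 of co-culture on monoculture. Of the genes past the threshold in both, 1304 were higher in both (309.8 expected by chance overlap), 1013 lower in both (244.3 expected) and 20 opposite. The co-culture effects with and without gefitinib correlated at 0.00411 ± 0.0308 across genes (Spearman -0.0398). Without gefitinib the changes had an SD of 0.2298 across genes, against a median standard error of 0.1425, so error limits this correlation. Of the genes past the threshold in both co-culture effects, 9 were higher in both (2.273 expected by chance overlap), 8 lower in both (1.018 expected) and 3 opposite.

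**Figure D4:**
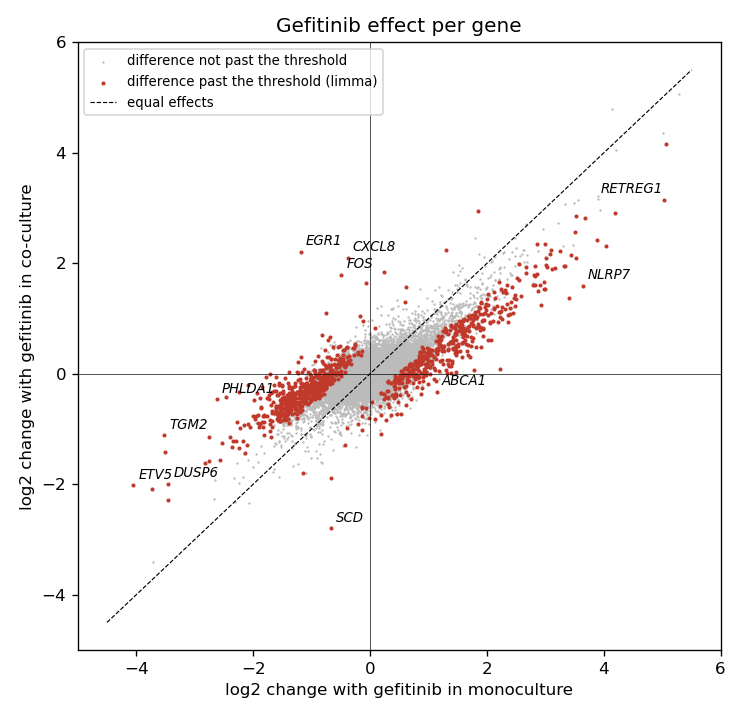
Log2 change with gefitinib in co-culture against that in monoculture, 1 point per gene, with the 983 genes whose effects differed by limma in red and a dashed line of equal effects. EGR1, FOS and CXCL8 lie at 2.21, 1.79 and 2.09 in co-culture, and SCD at -2.80.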

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

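The tests of MRC-5 RNA, of mixed cells and of handling, and the splits within gefitinib levels and further draws of free splits, were chosen only after the results they address were seen, and the liver X receptor targets were listed after SCD, SREBF1 and ABCA1 had been seen. The results below drew attention because the effect of gefitinib differed between co-culture and monoculture by a test of the difference itself (limma for genes, camera for lists).

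The difference passed for 983 genes. Of 100 free splits of the 12 arrays, 1 gave as many, the real one, and the highest other gave 351. For lists, 15 passed (6 with an estimated correlation), and 3 of the 100 splits gave as many, with 19 as the highest other. These counts depended on the draw: in 10 further draws of 99 other splits, 1 to 4 of 100 gave as many genes, with 34 to 5675 as the highest other, and 3 to 7 gave as many lists, with 17 to 22. Free splits can also put the gefitinib effect into the difference or the spread, so they are not used here to exclude chance. All 200 splits of the culture labels within each gefitinib level were also counted. For genes and for lists, 1 gave as many, the real one. The highest others were 796 genes, from labels exchanged at 1 gefitinib level, and 12 lists. These counts argue against culture labels without any effect. Splits that mix both cultures put the co-culture effect into the spread, so the counts do not test the difference of effects by itself. Early response and signalling genes with positive differences were EGR1 (3.40), CXCL8 (2.48), FOS (2.28), PHLDA1 (2.16), FOSL1 (2.05), ETV5 (2.04), DUSP4 (1.89), SPRY4 (1.60), DUSP6 (1.46), MYC (0.74) and CCND1 (0.72). Others were TGM2 (2.41), MALL (2.09), FOXD1 (1.92), ANKRD1 (1.86) and CCN2 (1.72). Negative differences were those of INHA (-2.14), SCD (-2.14), NLRP7 (-2.05), TPPP3 (-2.04), RETREG1 (-1.87), RGCC (-1.72), IL32 (-1.71), GASK1B (-1.69), ABCA1 (-1.47), IFIT2 (-1.46), TNNC1 (-1.46), WNT10A (-1.46), BMF (-0.86) and ERBB3 (-0.66). The values of DUSP4 and SPRY4 (above background on 0 of 3 arrays with gefitinib alone), GASK1B and WNT10A (0 of 3 with DMSO) and NLRP7 (0 of 3 in co-culture without gefitinib), and of TPPP3 and IL32 (1 of 3 in both groups without gefitinib), depend on the background level, and no bound was computed for differences of effects.

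Median differences of lists were 1.41 for ERK output, 0.85 for DNA replication, 0.80 for metallothioneins, 0.62 for mitosis, 0.54 for ribosome biogenesis, 0.44 for immediate early genes and 0.33 for YAP targets. They were -0.43 for both cell cycle exit and MHC class 1 genes, -0.42 for cholesterol synthesis, -0.35 for interferon and -0.32 for lysosome genes, and -0.24 for both fatty acid synthesis and epithelial genes. For FOXO and receptor feedback genes the median was -0.22. With an estimated correlation only ERK output, DNA replication, mitosis, ribosome biogenesis, cholesterol synthesis and lysosome genes passed camera. Under median scaling, where the median of all genes was 0.292, the medians of the lysosome (0.09), fatty acid (0.15), epithelial (0.13) and FOXO (0.01) lists turned positive. Of these only the lysosome list still passed camera (adjusted p = 0.00445, against 0.149, 0.25 and 0.118 for the others in that order). The medians of interferon (-0.05), MHC class 1 (-0.02), cholesterol (-0.02) and cell cycle exit genes (-0.14) moved toward 0. The ERK output median was 0.70 with no background correction.

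The first pattern is the smaller gefitinib effect in co-culture, seen for 772 of the 983 genes. MRC-5 RNA in the samples is argued against by the fibroblast markers, of which 0 of 18 tested were higher by limma in co-culture with gefitinib than with gefitinib alone, while COL1A2 was above background on 1 of 3 arrays in both groups and THY1, LUM and COL3A1 on 0, and it is excluded only as the whole cause, since DCN and COL6A3 were seen on 2 of 3 arrays, against 1 and 0. Array normalization is argued against as the whole cause for the ERK output genes, whose median difference was at least 0.6855 under 3 other normalizations. It stays open for raised genes. With median scaling the interferon median was 0.76 in monoculture and 0.93 in co-culture, and the lysosome median 0.31 and 0.45. The MHC class 1 median was 1.13 and 0.98. A mixture of unaffected and fully affected cells would leave each list the same share of its monoculture change. A first comparison of 3 growth lists with 3 raised lists gave shares differing by 0.0216 (permutation p = 0.5). A later one over 6 lists gave medians with a range of 0.2837 (permutation p = 0.006), from 0.359 for replication to 0.643 for MHC class 1 genes. Of these 6, replication and mitosis genes (0.566) also differed from each other (permutation p = 1e-04). Outside the 6, the medians were 0.282 for ribosome biogenesis, 0.446 for epithelial and 0.836 for JAK/STAT3 genes. All these permutations treat genes as independent, which they are not, so they leave a mixture open. No biological explanation was tested, and fibroblast signals, a change of medium, a washout or shorter exposure to gefitinib, and a handling difference marked by the WH in the co-culture titles stay open, since monocultures matched for these are not labelled.

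The second pattern is that immediate early genes were higher in co-culture with gefitinib. Handling shared by both co-culture groups is argued against by the co-culture without gefitinib, where 0 of 11 members passed limma and the list did not pass camera (adjusted p = 0.13). A mixture of unaffected and fully affected cells would put each gene between the levels of both kinds, whereas 4 of 11 members (FOS, FOSB, EGR1 and ZFP36) were called higher than in co-culture without gefitinib and than with gefitinib alone. The difference of the gefitinib effects on this list had an adjusted p of 0.0535 with an estimated correlation, against 6.75e-05 with the preset one. No biological explanation was tested, and fibroblast signals under EGFR inhibition, a washout or shorter exposure to gefitinib, and a step at harvest done for this group alone stay open.

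The third pattern is that SCD, SREBF1 and ABCA1, known targets of the liver X receptor, were higher in co-culture without gefitinib. Of 14 further targets listed before their values were seen, 10 were tested: their median was 0.3759, 8 were higher and 0 passed limma on their own, with a camera p of 6.27e-05 (0.0119 with an estimated correlation). Activity of this receptor is thus a hypothesis that the test could have excluded and did not. In co-culture with gefitinib against gefitinib alone, the same genes had a median of -0.0265 (camera p = 0.873, and 0.9 with an estimated correlation), with 4 of 10 higher. Their median in the difference of the gefitinib effects was -0.352 (camera p = 0.0218, and 0.1 with an estimated correlation). That difference is the co-culture effect with gefitinib minus the one without, so it largely restates the rise without gefitinib and is no separate result. The medium of the co-culture may differ from that of the monoculture per the labels. Medium, fibroblasts, DMSO against an unstated vehicle, and a handling difference marked by the WH in the co-culture titles stay open. Of these, fibroblasts, the WH and, per the labels, the EMEM were shared by the co-culture with gefitinib. There these 10 genes were not higher as a set, so such a cause would have to act differently with gefitinib.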

How the results depend on the processing

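All alternatives below were planned, and those for the chip could not be run. Over all of them, 423 of 612 calls of named genes and 44 of 76 calls of lists stayed past the threshold in the same direction wherever they were tested. In these counts an alternative that left a gene or list untested did not end its call. Of the calls, 2 genes and 0 lists reversed. For lists this direction is that of camera, relative to all other genes. Medians of some called lists did change sign under median scaling. Among them were lysosome genes in the difference (-0.32 to 0.09) and MHC class 1 genes in co-culture with gefitinib (-0.27 to 0.02). By comparison, 154 of 175 named calls held for gefitinib in monoculture, 121 of 159 in co-culture, 3 of 30 for co-culture without gefitinib, 83 of 133 with gefitinib and 62 of 115 for the difference. The cause was not tested except where given.

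Co-culture without gefitinib called 48 genes, against 124 with no background correction, 119 with the authors' normalized values, 85 with the strict filter, 17 with median scaling, 19 with the replicate number as a block and 4 with only the compared groups in the fit, where fewer arrays leave fewer degrees of freedom. The difference of the gefitinib effects called 983 genes, against 1475 with no background correction, 1668 with median scaling, 1462 with the authors' values, 1345 with the strict filter, 759 with no filter and 709 with the replicate number as a block. Asking also for a fold of at least 1.5 left 3289 genes in monoculture, 1411 in co-culture and 829 for co-culture with gefitinib, by its construction. An estimated correlation in camera left 8 of 14 lists in monoculture, 3 of 11 for co-culture without gefitinib and 6 of 15 for the difference. The correlation of the gefitinib effects across genes, 0.79, became 0.836 with no background correction, 0.836 with the authors' values, 0.828 with the strict filter, 0.752 with no filter and 0.754 with median scaling, and the correlation of the co-culture effects across genes became -0.0607 with median scaling. HOPX reversed in the difference with the mean of its probes, from -0.52 to 0.17 (adjusted p = 0.685 by limma, over alternatives 0.02 to 0.685).

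Leaving out 1 array gave 4890 to 5057 genes in monoculture, 2023 to 2369 in co-culture, 11 to 26 for co-culture without gefitinib, 1096 to 1568 with gefitinib and 575 to 955 for the difference. Lists ran from 14 to 15, 24 to 25, 7 to 13, 11 to 13 and 13 to 15, the correlation of the gefitinib effects across genes from 0.759 to 0.791, and the correlation of the co-culture effects across genes from -0.0119 to 0.0172. The count for co-culture without gefitinib was 18, 21 and 18 without DMSO arrays 1, 2 and 3, and 22, 26 and 11 without arrays 1, 2 and 3 of that co-culture, and its lists numbered 7 without array 2. For co-culture with gefitinib the count was 1168 and 1096 without its arrays 2 and 3, and for the difference 629 and 575. The lowest correlation, 0.759, came without array 1 of co-culture with gefitinib. F3 in co-culture without gefitinib ran from -0.61 to 0.01 and reversed without DMSO array 1 (0.0098, adjusted p = 0.982 by limma, over alternatives 0.00328 to 0.982), where another of its probes became the brightest (10.66 against 10.65). The fold of a gene with little signal over background is limited by it. Without background correction the median difference was 0.6994 for ERK output against 1.41, 0.5515 for mitosis against 0.62 and 0.7445 for replication against 0.85, and the cause was not tested.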

Other observations

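All tests in this part were chosen before the data were examined. The replicate numbers do not pair the arrays: over 18 pairs with the same number, residual correlations ran from -0.038 to 0.039. Residual correlations with the other groups were also averaged by replicate number, and the own number had the highest mean for 4 of 12 arrays.

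Other splits of the arrays of each pair of groups were counted, where 10 splits are too few for a share under 0.05. The real split gave 5511 genes for gefitinib in monoculture and the highest other 0, 2710 and 0 in co-culture, 48 and 1 for co-culture without gefitinib, and 1820 and 0 for co-culture with gefitinib, with 1 of 10 splits as large each time. For lists the real split and the highest other gave 14 and 9, 24 and 11, 11 and 1, and 12 and 7, again with 1 of 10 as large.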
